A study of Mus musculus with 4 samples.

How the data were processed

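Gene expression was measured in mouse osteoclast cultures on 4 Affymetrix arrays, with 2 arrays for wild-type cultures and 2 for NFATc1-deficient cultures. Per the labels' protocols, osteoclast precursors were sorted from whole bone marrow of C57BL/6 mice as CD11b-negative, CD3e-negative, B220-negative cells that were positive for c-Kit and c-Fms. Cells were plated at 20000 per well and cultured for 3 days with M-CSF and RANKL, the cytokines that drive osteoclast formation. Each array carried RNA from a pool, of 3 mice for replicate 1 and of 4 mice for replicate 2, per the labels' protocols. The series' design text calls the starting cells bone marrow macrophages and the replicates biological. Both genotypes carried floxed Nfatc1 alleles, and the deficient mice also carried the Mx-Cre transgene, in which poly I:C treatment induces the recombinase. Whether the wild-type mice also received poly I:C, and which exons were removed, was not given in the sources used here.

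The deposited values were probe set intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes. Biotin-labelled cRNA was prepared by the standard Affymetrix protocol, per the labels' protocols. MAS5 combines the probes of a probe set into 1 signal per array and multiplies each array by 1 factor. The scaling target was read from the values: the mean of each array without the top and bottom 2% lay between 500.186 and 500.211. The MAS5 version and detection calls were not given in the sources used here, so the standing of a low signal against background is unknown. The number of arrays limits the precision of every comparison.

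Probe sets were named from the platform annotation supplied with the values. Of 22690 probe sets, 20393 had 1 gene symbol, 691 had several and 1606 had none. Entrez numbers matched 20364 of the probe sets with 1 symbol to the RefSeq names of assembly GRCm38, and 0 symbols changed. No gene was named from a probe set with several symbols, and no genome was used here, so no positions are given.

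Signals were analysed as log2(signal + 23.3), where 23.3 is the 25th percentile of all values. Changes on this scale understate those of dim genes, and fold values are ratios of mean signals unless the log2 scale is named. After 64 control probe sets were left out, probe sets with a mean above the 40th percentile were kept, which left 13578. They were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, for NFATc1-deficient minus wild-type. The test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Every adjusted p given for a gene comes from this fit. For genes with several probe sets the brightest tested one was used, and the text states where another differed in sign or in passing the threshold.

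There were 23 gene lists. They covered resorption effectors, reported NFATc1 targets, vacuolar ATPase subunits, cell fusion, RANK signalling and transcription factors, costimulatory and calcium signalling, negative regulators of osteoclast formation, and podosome and actin cytoskeleton. They also covered lysosomal proteins, oxidative phosphorylation, glycolysis, cholesterol biosynthesis and uptake, cell cycle, inflammatory cytokines, the type I interferon response, and RNA quality and stress. The remaining lists held markers of macrophages, antigen-presenting cells, granulocytes, progenitors, lymphoid cells, erythroid cells and stromal cells. The 19 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. These p-values were adjusted over the 19 lists.

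The genes named in the text were chosen by rule. They were Nfatc1, the 12 genes with the largest fall and the 12 with the largest rise among those past the threshold with both deficient signals outside the wild-type signals, up to 4 members of each list with the largest absolute change, and a short set of osteoclast and reference genes. This rule, the lists, the tests and the other settings were fixed before the data were examined. Some genes of that set were not analysed here, and Gapdh was represented only by control probe sets.

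The scripts were tested on simulated data for this comparison with all 13578 probe sets. At a 1.5-fold change 5 of 50 changed probe sets were recovered, at 2-fold 33 of 50, at 4-fold 49 of 50 and at 8-fold 50 of 50. Unchanged probe sets made up 8 of 145 calls. Camera with the preset correlation called 20 of 20 lists shifted by 0.5 on the log2 scale, and camera with the estimated correlation called 0 of 20. Of 200 unshifted lists, 4 had an unadjusted p under 0.05 with the preset correlation. The simulated probe sets varied independently, so false calls among lists of correlated genes were not measured. Alternatives covered the scaling, the pseudocount, the filter, the variance trend, a replicate block, leaving out each array, a fold rule without a test, and other settings for the list tests.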

Results

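NFATc1 is the transcription factor that drives the osteoclast program downstream of RANK, and the series compared wild-type and NFATc1-deficient cultures after 3 days with M-CSF and RANKL. Expression was measured in 2 wild-type and 2 NFATc1-deficient cultures, each from a separate pool of mice. The arrays had median signals of 130, 112, 114 and 125. Arrays of the same genotype correlated more closely across probe sets (r of 0.983 for wild-type and 0.985 for deficient cultures) than arrays of different genotypes (0.966 to 0.970). In both genotypes Xist was high and the Y-linked gene Eif2s3y low in replicate 1, and the reverse in replicate 2, so the pools differed in sex by replicate number.

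Nfatc1 signal was lower in the deficient cultures and was at least 52.1% of the wild-type mean for both probe sets on both deficient arrays. The brighter probe set fell from 5790.2 ± 504 to 3558 ± 763 (mean signal ± SD, n = 2), a log2 change of -0.71 (SE 0.15, adjusted p = 0.0102). The dimmer probe set changed by -0.55 (SE 0.12, adjusted p = 0.0126). Without NFATc1-deficient replicate 1 the adjusted p of the brighter probe set was 0.0881, and without the variance trend it was 0.0600. The position of the probe sets relative to the deleted exons was not analysed here, so what they show of the deletion itself is open.

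Several osteoclast genes fell to a small part of their wild-type signal, and the decoy receptor of RANKL rose. Of 13578 probe sets tested, 1546 were lower and 1739 were higher in the deficient cultures. Among these, 112 were at least 4-fold lower and 20 at least 4-fold higher by the ratio of mean signals, and 87 and 11 on the log2(signal + 23.3) scale. With 1 probe set per gene, 924 of 7801 genes were lower and 998 higher. Slc9b2, a sodium-proton exchanger of osteoclasts, fell from 7704 ± 560.5 to 317 ± 276 (n = 2), a log2 change of -4.79 (SE 0.47, adjusted p = 0.000381). Tnfrsf11b, which encodes the RANKL decoy receptor osteoprotegerin, rose from 18.5 ± 5.94 to 786 ± 133 (n = 2), a log2 change of 4.27 (SE 0.23, adjusted p = 4.99e-05). The median change of lower probe sets was -0.81 between the replicate 1 arrays and -0.71 between the replicate 2 arrays, and that of higher probe sets was 0.68 and 0.67. Without NFATc1-deficient replicate 1 the counts were 933 lower and 849 higher.

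**Figure D1:**
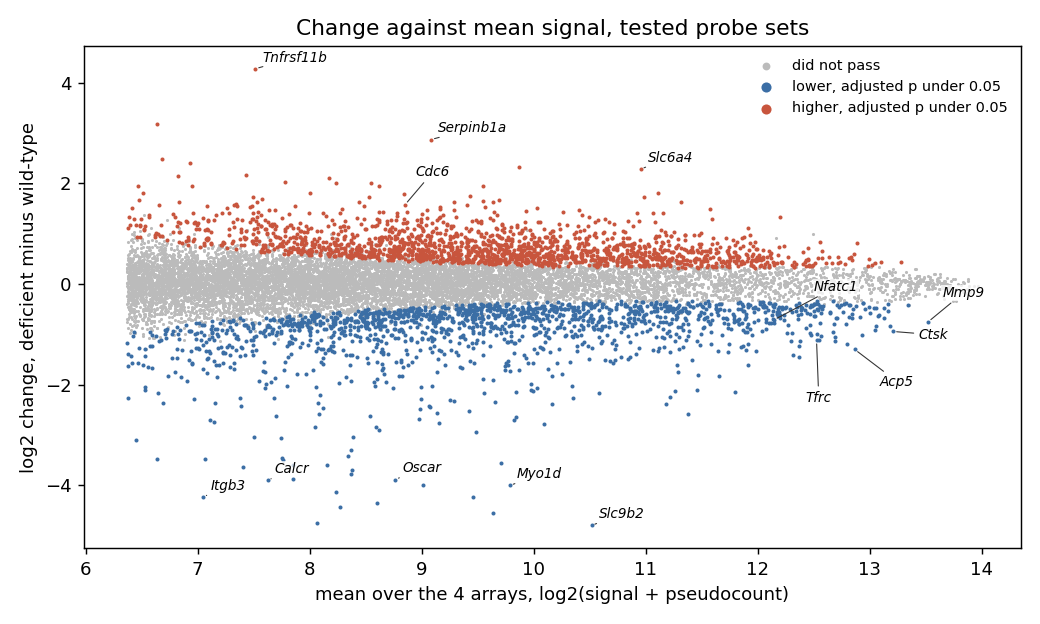
Log2 change, NFATc1-deficient minus wild-type, against the mean log2 signal for the 13578 tested probe sets, with 1 point per probe set and selected genes named. The 1546 lower probe sets reach -4.79 for Slc9b2, and the 1739 higher probe sets reach 4.27 for Tnfrsf11b.

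On the log2(signal + 23.3) scale the largest falls after Slc9b2 were in the metalloreductase Steap4 (-4.75), the thrombin receptor F2r (-4.54), integrin beta 3 (Itgb3, -4.23), metallothionein 3 (Mt3, -4.23), the myosin Myo1d (15.1-fold lower in mean signal), Akr1c18 (-3.99), the calcitonin receptor Calcr (-3.90), Oscar (-3.88), Mst1r (-3.86), Edil3 (-3.77) and Plpp1 (-3.68). Itgb3, which pairs with integrin alpha V on osteoclasts, fell from 553 ± 81.7 to 7.4 ± 3.96 (n = 2), below the pseudocount. The order is that of this scale alone, because deficient signals near or below the pseudocount, as for Itgb3, Steap4 and Calcr, leave the size of these falls unknown. Rab38 changed by -3.54, Adcy3 by -2.16 and Rhoc by -1.83, and each passed. The largest rises after Tnfrsf11b were in the protease inhibitor Serpinb1a (2.87), the metalloproteinase Adamts5 (2.48), Ndrg4 (2.33), the serotonin transporter Slc6a4 (2.28), Slc6a12 (2.14), the cytokine signalling inhibitor Socs3 (2.10), Sox4 (2.03), B4galt4 (1.95), Mgst2 (1.94), Dyrk3 (1.94) and the heat shock gene Hspa1b (1.94). The order of the rises is also that of this scale alone. Wild-type mean signals lay near or below the pseudocount for Tnfrsf11b (18.5), B4galt4 (21.8) and Adamts5 (26). By the ratio of mean signals Adamts5 (8.58) lay above Serpinb1a (8.09). Other probe sets did not pass for Sox4 (-0.27), Socs3 (0.77) and Adcy3 (-1.04).

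**Figure D2:**
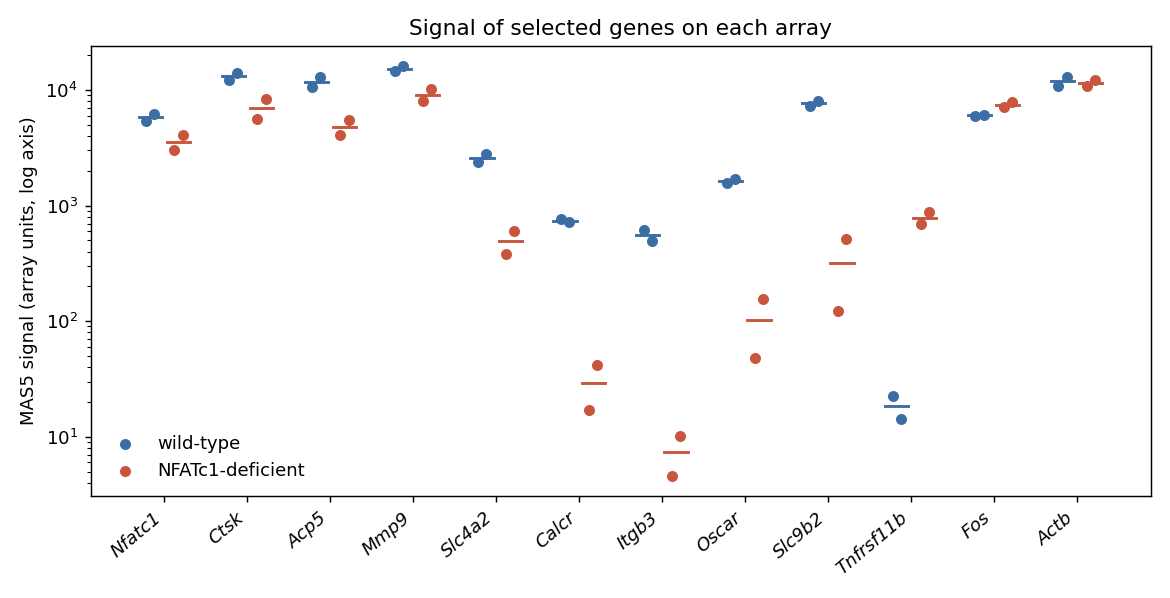
MAS5 signal on a log axis for 12 selected genes, with 1 point per array and a bar at the mean of each group (n = 2). Slc9b2 lies at 7704 in wild-type and 317 in NFATc1-deficient cultures, whereas Tnfrsf11b lies at 18.5 and 786.

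The machinery of bone resorption fell as a group. All 14 tested resorption effectors fell, over all genes and adjusted over the list alone, with a median change of -1.41 (camera adjusted p = 4.97e-14, and adjusted p = 0.481 with an estimated correlation). Cathepsin K (Ctsk) changed by -0.94, tartrate-resistant acid phosphatase (Acp5) by -1.30, Mmp9 by -0.75 and the anion exchanger Slc4a2 by -2.38. Without NFATc1-deficient replicate 1 the adjusted p was 0.0749 for Ctsk and 0.136 for Mmp9. All 11 reported NFATc1 targets fell, also adjusted over the list alone, with a median of -1.22 (camera adjusted p = 1.49e-10, and adjusted p = 0.481 with an estimated correlation). The target list includes Nfatc1 itself, the targeted gene, and shares 9 of its tested genes with the resorption list. Its remaining gene is Oscar, so this list is not separate support. Among 16 subunits of the vacuolar ATPase, which acidifies the resorption space, 14 fell over all genes and adjusted over the list alone, with a median of -0.79 (camera adjusted p = 1.49e-10, and adjusted p = 0.481 with an estimated correlation). Atp6v1e1 changed by -1.45, Atp6v1d by -1.33, Atp6v1h by -1.24 and Atp6v1a by -1.18.

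The podosome and lysosome lists were lower in part, and the fusion list did not pass. Of 30 podosome and actin genes, 13 fell and 17 did not pass, the same counts adjusted over the list alone (median -0.20, camera adjusted p = 6.06e-06, and adjusted p = 0.481 with an estimated correlation). Besides Itgb3 and Myo1d, the small GTPases Rhoc (-1.83) and Rac2 (-1.80) fell. Of 26 lysosomal genes, 12 fell, 2 rose and 12 did not pass, and adjusted over the list alone 14 fell and 2 rose (median -0.31, camera adjusted p = 0.000238, and adjusted p = 0.481 with an estimated correlation). The enzymes Glb1 (-2.02), Hexa (-1.23), Gaa (-1.05) and Tpp1 (-0.94) fell, Gaa not without the filter or without the variance trend. Of 12 fusion genes, 5 fell and 1 rose, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0848, and 0.0425 without wild-type replicate 2). Tspan5 fell from 429 to 203, Ocstamp changed by -0.98, and the metalloprotease Adam8 rose by 0.84. Another Tspan5 probe set did not pass (-0.58).

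Signalling and transcription factor genes moved in both directions. Of 24 RANK signalling genes and transcription factors, 7 fell and 2 rose, and adjusted over the list alone 8 fell and 3 rose (camera adjusted p = 0.220). Ppargc1b, a coactivator of mitochondrial genes, changed by -2.53, the calcineurin regulator Rcan1 by -2.06, Fosl2 by -1.12 and the repressor Prdm1 by -1.12. The RANK gene Tnfrsf11a had a change of 0.27 (adjusted p = 0.155, with -0.14 at another probe set) and Fos of 0.31 (adjusted p = 0.0623). Fos passed with quantile scaling and with replicate number as a block. Of 23 costimulatory and calcium signalling genes, 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.112). Oscar and the adaptor Lcp2 (-1.16) fell, the adaptor Blnk rose by 0.70, and Fcgr1 had a change of 0.53 (adjusted p = 0.552). Of 14 negative regulators of osteoclast formation, 3 rose and 11 did not pass, also adjusted over the list alone (camera adjusted p = 0.105, but 0.0381 with replicate number as a block and 0.0273 without wild-type replicate 1). Those that rose were Tnfrsf11b, Socs3 and Id2 (0.89), while another Id2 probe set had 0.21 and did not pass. Id1 had a change of 0.64 (adjusted p = 0.116) and Irf8 of 0.15 (adjusted p = 0.820).

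Mitochondrial energy genes fell and cell cycle genes rose. Of 30 oxidative phosphorylation genes, 23 fell over all genes and 26 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 2.75e-13, and adjusted p = 0.481 with an estimated correlation). Ndufs3 changed by -1.06, Ndufs8 by -1.01, Ndufa4 by -0.93 and Uqcrfs1 by -0.90. Another Ndufs8 probe set did not pass (-0.35). Of 28 cell cycle genes, 24 rose over all genes and 27 adjusted over the list alone, with a median of 0.86 (camera adjusted p = 3.82e-15, and adjusted p = 0.481 with an estimated correlation). The replication genes Cdc6 (1.57) and Mcm4 (1.25), the mitotic kinase Bub1 (1.28) and cyclin D1 (Ccnd1, 1.16) rose, although another Ccnd1 probe set did not pass (0.77). Of 13 granulocyte markers 4 rose, also adjusted over the list alone, and the list did not pass (median 0.59, camera adjusted p = 0.0600). Those that rose were S100a8 (1.41), S100a9 (1.34), Chil3 (1.26) and Ngp (1.04), and S100a9 had an adjusted p of 0.0486. Between the replicate 1 arrays and between the replicate 2 arrays the changes were 2.25 and 0.57 for S100a8, 2.53 and 0.15 for S100a9, and 1.79 and 0.29 for Ngp. Without NFATc1-deficient replicate 1, S100a9, Ngp and Chil3 no longer passed, and S100a8, S100a9 and Ngp did not pass without the filter or without the variance trend (adjusted p of S100a8 up to 0.0634). The granulocyte list passed without wild-type replicate 1 (median 0.69, camera adjusted p = 0.0454), wild-type replicate 2 (0.91, 0.0121) or deficient replicate 2 (1.06, 4.73e-05), and with replicate number as a block (0.00324), but without deficient replicate 1 it had a median of 0.20 (0.724).

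Glycolysis genes moved in both directions, and the cholesterol list was lower by camera with the preset correlation. Its count of 2 of 16 genes that fell stands beside 924 of 7801 over all genes. Of 12 glycolysis genes, 3 fell and 2 rose, and adjusted over the list alone 4 fell and 2 rose (camera adjusted p = 0.193). Hexokinase 1 (Hk1) changed by -1.36 and Pfkp by -0.87 (-0.42 at another probe set, which did not pass), whereas hexokinase 2 (Hk2) rose by 0.54 and Slc16a3 had a change of 0.53 (adjusted p = 0.235). Of 16 cholesterol genes, 2 fell, also adjusted over the list alone (median -0.22, camera adjusted p = 0.0310, and adjusted p = 0.481 with an estimated correlation). The cholesterol list did not pass with replicate number as a block (adjusted p = 0.0506), with median scaling (0.0932), with the stricter filter (0.0576), with the mean of all probe sets per gene (0.0551) or without either the wild-type or the deficient replicate 2 (0.109 for each). The genes that fell were Nsdhl (-0.66) and Hmgcs1 (-0.57). Tm7sf2 (-0.59, adjusted p = 0.0940) and Dhcr7 (-0.47, adjusted p = 0.154) did not pass. Hk2 and Hmgcs1 lost the call when single arrays were left out.

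**Figure D3:**
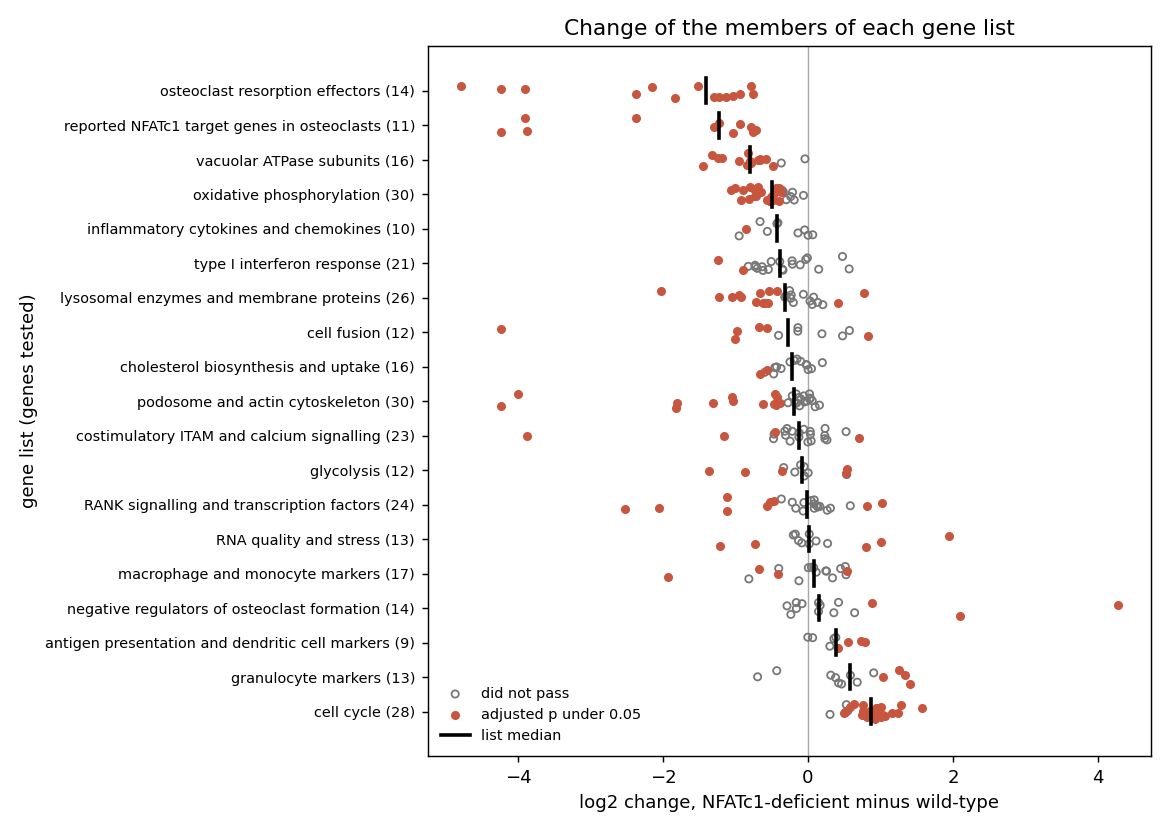
Log2 change, NFATc1-deficient minus wild-type, of each tested gene of the 19 lists, with filled points for genes past the threshold, open points for those that were not and a bar at the list median. The medians run from -1.41 for resorption effectors to 0.86 for cell cycle genes.

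Macrophage markers moved in both directions. By camera with the preset correlation the antigen presentation list was higher and the interferon list was lower. The interferon count of 2 of 21 genes that fell stands beside 924 of 7801 over all genes. Of 17 macrophage and monocyte markers, 3 fell and 1 rose, and adjusted over the list alone 5 fell and 1 rose. The median of this list was 0.08, its mean -0.07 and its camera direction lower (adjusted p = 0.682). Apolipoprotein E (Apoe) changed by -1.94, Cd68 by -0.68, and the M-CSF receptor Csf1r by -0.41 (adjusted p = 0.0457), with -0.88 and -0.89 for its other probe sets. Cd14 rose by 0.54, and Clec7a had a change of -0.82 (adjusted p = 0.0551). Of 9 antigen presentation and dendritic cell genes, 4 rose, also adjusted over the list alone (median 0.38, camera adjusted p = 0.0188, and adjusted p = 0.481 with an estimated correlation). They were the MHC class II genes H2-Aa (0.79), H2-Ab1 (0.55) and H2-Eb1 (0.42), and Cd40 (0.74, with 0.43 at another probe set, which did not pass). Of 21 interferon response genes, 2 fell over all genes and 0 adjusted over the list alone (median -0.39, camera adjusted p = 0.0384, and adjusted p = 0.678 with an estimated correlation). They were Oasl2 (-1.24) and Ifi27l2a (-0.89), while Irf7 (-0.82, adjusted p = 0.110) and Ifi47 (-0.73, adjusted p = 0.113) did not pass. Of 10 inflammatory genes, Ccl6 fell (-0.86, with -0.34 at another probe set, which did not pass), also adjusted over the list alone (camera adjusted p = 0.104, and 0.0220 without wild-type replicate 2). Cxcl10 (-0.95, adjusted p = 0.0632), Csf1 (-0.56, adjusted p = 0.306) and Tnf (-0.66, adjusted p = 0.504) did not pass. Irf7, Ifi47, Cxcl10 and Clec7a passed with median scaling and with replicate number as a block, whereas Cd40 did not pass with the block. Csf1r, Cd14, Cd68, H2-Ab1, H2-Eb1, Cd40, Oasl2, Ifi27l2a and Ccl6 lost the call when at least 1 of the arrays was left out. The interferon list did not pass with the stricter filter (adjusted p = 0.319) or without wild-type replicate 1 (0.701) or deficient replicate 2 (0.358), and the antigen presentation list did not pass without a filter (0.0715) or without wild-type replicate 2 (0.0818).

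Markers of other marrow cells and reference genes were also measured. None of the 4 tested progenitor and mast cell genes passed, with changes of 0.67 for Itga2b, 0.63 for Cd34, 0.38 for Gata2 and 0.24 for Myb. Itga2b and Cd34 passed with median scaling, and Cd34 also with replicate number as a block. Of 2 lymphoid genes Il7r rose (1.15) and Ighm had a change of 0.18 (adjusted p = 0.694). Of 2 genes of the erythroid list the transferrin receptor Tfrc fell (-1.12, with -2.13 and -2.71 for its other probe sets) and Epor had a change of 0.52 (adjusted p = 0.214). Tfrc had a mean signal of 8739 in the wild-type cultures, so its fall is not read as a loss of erythroid cells. Neither of 2 stromal genes passed, with 0.17 for Dcn and -0.10 for Col1a2. Among 13 stress genes, 2 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.787). Hspa1b, Hspa1a (1.01) and Ier3 (0.80) rose and Egr1 fell (-1.22), and Hspa1a and Ier3 lost the call when single arrays were left out. Beta actin (Actb) had a change of -0.05 (adjusted p = 0.811) at its brightest probe set and of -1.08 at another, which passed. The control probe sets for Gapdh had a mean difference of -0.06.

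With an estimated correlation, camera called 0 of the 19 lists, with 0 at an unadjusted p under 0.05, against 10 with the preset correlation. Among those 10 the estimate ran from 0.05 for cholesterol to 0.84 for interferon, with 0.81 for resorption effectors and 0.48 for cell cycle genes. Their preset p-values assume 0.01. The 0 of 20 called in simulation came from independent probe sets shifted by 0.5, so it does not show how correlated lists fare. With an estimated correlation, lists added later had unadjusted camera p of 0.0197 (ribosome biogenesis), 0.163 (citric acid cycle) and 0.534 (mitochondrial ribosome). With median scaling 14 of the 19 passed, among them fusion, RANK signalling, costimulatory signalling, negative regulators and granulocyte markers, and cholesterol did not.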

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

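The comparison of hybridisation controls between genotypes was among the tests chosen after the values were seen. These controls are bacterial or phage transcripts added in fixed amounts to every sample, and they stand outside the comparison of mouse genes. They were higher on both NFATc1-deficient arrays than on both wild-type arrays, by 0.32 on the log2 scale for BioB, 0.30 for BioC, 0.26 for BioD and 0.22 for Cre. Over all 4 controls the means were 9.39 and 9.58 on the wild-type arrays and 9.62 and 9.92 on the deficient arrays, so arrays of the same genotype differed about as much as the genotypes did. With 2 arrays against 2, a given order of this kind arises by chance in 1 of 6 cases for a single control, and the 4 controls are added together and are not independent.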

How the results depend on the processing

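The settings compared in this part were planned, and none of the tests of this part was chosen after its result was seen. No probe set past the threshold changed sign under any setting. Under quantile or median scaling, either pseudocount and the stricter filter, 1408 to 1699 probe sets were lower and 1639 to 1854 higher. Without a filter 1140 were lower and 1157 higher. Without the variance trend 1067 were lower and 1015 higher, so 51.2% of calls were lower against 47.1% in the reported test, and Nfatc1 had a change of -0.71 with an adjusted p of 0.0600. At least 2-fold in every pair of arrays, without a test, gave 273 lower and 125 higher. With an estimated correlation 0 lists passed. Of the named genes that had passed, besides Nfatc1, 14 no longer did without a filter and 13 without the variance trend, under both S100a8, S100a9, Ngp, Gaa, Csf1r, Cd14, Hk2, H2-Eb1, Ier3 and Ifi27l2a. With the stricter filter cholesterol and interferon did not pass, nor did antigen presentation without a filter. With median scaling 14 lists passed: cell fusion (adjusted p = 0.0205), RANK signalling (0.0464), costimulatory signalling (0.0451), negative regulators (0.00110) and granulocyte markers (0.000315) gained the call and cholesterol (0.0932) lost it.

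Leaving out each array in turn, with a lone array assumed to vary like the other group, gave 933 to 1546 lower, 849 to 1953 higher, 9 to 11 lists, and a change of Nfatc1 from -0.93 to -0.49. Of the named genes that had passed, besides Nfatc1, 14 no longer did without NFATc1-deficient replicate 1 (Ctsk, Mmp9, Cd68 and S100a9 among them), 9 without deficient replicate 2, 5 without wild-type replicate 1 and 7 without wild-type replicate 2. Of these 18 genes, 11 lost the call for at least 2 of the arrays in turn: Csf1r, Cd14, Hk2, H2-Eb1, H2-Ab1, Cd40, Ier3, Ccl6, Oasl2, Ifi27l2a and Hspa1a. Lists that lost the call were antigen presentation without wild-type replicate 2, cholesterol without replicate 2 of either genotype, and interferon without wild-type replicate 1 or deficient replicate 2. Granulocyte markers gained it without any array but deficient replicate 1, negative regulators without wild-type replicate 1, and fusion and inflammatory genes without wild-type replicate 2. Values that changed sign, none of which had passed, ranged from -0.18 to 0.074 for Actb, -0.25 to 0.046 for Col1a2, -0.48 to 1.53 for Fcgr1, -0.16 to 0.52 for Ighm, -0.42 to 0.71 for Irf8, -0.44 to 0.92 for Myb and -1.76 to 0.44 for Tnf. The list medians ranged from -0.079 to 0.26 for macrophage markers and 0.042 to 0.068 for stress genes, where the direction of camera turned.

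The labels tie a replicate number to the size of the pool, 3 or 4 mice, in both genotypes, and name no shared litter, batch or day for it, so it was not used as a pairing in the reported test, although the pools also differed in sex by that number. The differences of replicate 1 and 2 correlated across genes at r = 0.13 (rho = 0.03) between genotypes. With the replicate block 1805 probe sets were lower and 2066 higher, and Nfatc1 had a change of -0.71 with an adjusted p of 0.000201. With it 11 lists passed, with granulocyte markers (0.00324) and negative regulators (0.0381) gained and cholesterol (0.0506) lost. Among the named genes 6 gained the call with the block (Irf7, Ifi47, Cxcl10, Clec7a, Fos and Cd34) and Cd40 lost it.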

Other observations

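The tests of incomplete excision, of compression at Nfatc1, of probe set position, of scaling and of granulocyte precursors, and the check of the comparison of dimmer and brighter probe sets, were chosen after the result was seen, as were the ribosome, citric acid cycle and mitochondrial ribosome lists, whose own values had not been seen.

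Genes for building ribosomes rose in the deficient cultures. Of 38 tested ribosome biogenesis genes 24 rose, with a median change of 0.50 (camera p = 5.54e-12, and p = 0.0197 with an estimated correlation), including Nop58 (1.20) and Nop56 (1.00). Their median lay at percentile 100 of 10000 random lists matched on signal. Myc, named after its value was seen, rose by 1.02. Citric acid cycle genes fell: 9 of 16, with a median of -0.51 (camera p = 1.42e-06, and p = 0.163 with an estimated correlation), including Ogdh (-1.01) and Dlat (-0.83), at percentile 0 of the random lists. Of 38 mitochondrial ribosome genes 2 fell, with a median of -0.07 at percentile 7.83 of the random lists. A fall was not detected for this list (camera p = 0.268, and p = 0.534 with an estimated correlation).

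Xist and Y-linked genes separated the replicate numbers in both genotypes. Xist had signals of 3595 and 106 in wild-type replicates 1 and 2 and 2690.0 and 111 in deficient replicates 1 and 2. Eif2s3y had 14.4 and 1147 against 6.5 and 1049.7. Of the 87 probe sets at least 4-fold lower on the log2 scale, 70 had a higher signal in deficient replicate 2 than in replicate 1. This share was not compared with that of all probe sets and was not tested against the sex of the pools.

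Many lower probe sets retained less of the wild-type signal than Nfatc1 did. Incomplete excision would leave wild-type-like cells. If signals add over cells and these cells express genes as in a wild-type culture, they retain at least as much of every other transcript. However, 30.1% of the lower probe sets retained less than the lowest Nfatc1 retention of 52.1%. This argues against incomplete excision as the whole cause only under those conditions, which were not tested. Nfatc1 (3018.2 and 4097.9 at the brighter probe set), like most probe sets at least 4-fold lower, had less signal in deficient replicate 1 than in replicate 2. Whether the pools differed in excision was not tested. Compression near the brightest signals is argued against as the whole cause. Of 530 probe sets at least as bright as Nfatc1 in wild-type cultures, 22 (4.15%) retained less than the lowest Nfatc1 retention. A contribution of compression stays open. The change of the dimmer Nfatc1 probe set was 0.17 above that of the brighter one, against a median of -0.15 for such differences over bright genes. The SE of 0.19 treats the probe sets as independent although they share the same arrays, so it does not decide this. Probe sets outside the deleted part of the gene also remain a candidate explanation, since 0 of them had a position in the tables used.

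The bright osteoclast genes Ctsk, Acp5 and Mmp9 had small falls beside those of genes such as Slc9b2. Compression near the brightest signals may contribute: among genes with several lower probe sets, a dimmer probe set fell more than the brightest in 61 of 81 genes in the top 10% of signals and in 85 of 148 genes of middle signals (Fisher's exact test, two-sided, p = 0.00942). Genes entered that test by calls that the change itself decides, but without a pseudocount, on genes chosen by the mean change of their probe sets, the counts were 47 of 58 and 43 of 72 (Fisher's exact test, two-sided, p = 0.0125). Both tests used all such genes, not the osteoclast genes alone. The difference in how much osteoclast and other genes depend on NFATc1 was not tested.

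Cell cycle genes rose by a median of 0.86. Quantile and median scaling left a median of at least 0.84. However, they shifted the genotype difference over all probe sets by only -0.003 and 0.010, so they decide nothing. Taking off the mean difference of the hybridisation controls (0.28) left 0.58. Both values were known when this step was chosen, and the controls differed about as much within genotypes, so a scaling error stays open. More granulocyte precursors stay open, and the sort for CD11b-negative, c-Kit-positive cells does not decide this. Cell cycle genes differed by 0.16 between the wild-type replicates and granule genes by 0.96, but the granule genes did not pass between genotypes (0.40, adjusted p from 0.432 to 0.555), and S100a8 (-0.69) and S100a9 (-1.29) ran the other way between those replicates. The genotype may underlie the rise, but this stays a hypothesis, because poly I:C treatment of the wild-type mice was not given in the sources used here.

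The count of 3285 probe sets past the threshold came from the real grouping, and the highest of the other groupings of the 4 arrays gave 3. The real grouping was 1 of 3 such splits, which are too few for a share under 0.05. Each of the other groupings put arrays of both genotypes in each group. The genotype difference then widened the spread within groups, which by itself keeps such counts low, so this comparison is not support for the count.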
